A study of Mus musculus with 4 samples.

How the data were processed

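Single-nucleus RNA sequencing was done on whole hearts of male wild-type C57BL/6J mice, 1 heart per library. Every heart came from offspring injured at day 1 after birth and was taken 21 days after the injury. Fathers had been injured (2 libraries) or had not (2 libraries), per the labels. Per the labels, hearts were snap frozen, blood cells were excluded by sorting with a Ter119 antibody, and nuclei were loaded at a target of 10000 per library on a droplet kit that reads the 3' end of transcripts. The identity of the fathers and the litters of the offspring are not given in the sources used here.

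The authors made the matrices with Cell Ranger 6.0.1 (per the file headers) and name Seurat 4.0 among their tools. The deposited matrices hold raw UMI counts per gene and nucleus barcode, whole numbers with no normalization, for barcodes that the authors had already called as nuclei. The lowest total per barcode was 500 or 501 UMIs in each library. The features are 21884 genes, and 21779 of their identifiers are in the GENCODE M21 annotation of the GRCm38 build. The build and annotation behind the counts are not given in the sources used here. Positions from that annotation serve to identify genes and to find the genes within 1000000 bases of Slc15a2. The list of features holds no Xist, so the recorded sex was checked with Y-linked genes only.

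The choices in this paragraph and in the next were made before the data were examined, except where stated. Barcodes with fewer than 500 UMIs, fewer than 300 genes or at least 5% mitochondrial UMIs were removed. Doublets were marked in each library by Scrublet, run through scanpy 1.11.5, at its automatic threshold. Counts were scaled to 10000 UMIs per nucleus and log-transformed, 3000 variable genes were taken, and 30 principal components were computed over the 4 libraries together. Leiden clustering (leidenalg 0.10.2) at resolution 1.0 used 20 nearest neighbours. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used. Each of the 25 clusters was named by the highest mean fold of 17 lists of marker genes (cardiomyocyte, fibroblast, vascular endothelial, endocardial, lymphatic endothelial, pericyte, smooth muscle, macrophage or monocyte, neutrophil, T or NK lymphocyte, B lymphocyte, mesothelial or epicardial, Schwann or glial, adipocyte, erythroid, skeletal muscle and lung epithelial), with 20 CPM (UMIs of a gene per 1000000 UMIs) added before each fold and at least 3 markers required. Names mark likeness to a cell type by these lists. After the clusters were seen, 3 were left unnamed: 1 carried endocardial and fibroblast markers together, 1 scored best for neutrophil markers but was led by genes of other myeloid cells, and 1 scored best for erythroid markers but was led by cell cycle genes in most nuclei.

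The library, that is the heart, was the unit of replication. Shares of nuclei by class were tested with edgeR 4.0.16 (quasi-likelihood test, R 4.3.3) on the number of nuclei per class and library, with Benjamini-Hochberg adjustment over 14 groups of nuclei. For genes, counts were summed over the nuclei of a class in each library. A class was tested if every library held at least 50 of its nuclei, which left 7 classes. Mesothelial-like and T or NK lymphocyte-like nuclei, planned for gene tests, fell short of 50 in at least 1 library and were not tested. Genes with low counts were removed (filterByExpr, minimum count 10), libraries were scaled by TMM (as are the mean CPM values per group in the text), and the edgeR quasi-likelihood test compared offspring of injured fathers with offspring of uninjured fathers. Values past an adjusted p of 0.05 are called higher or lower. All tests were two-sided. All nuclei of a library were also summed and tested in this way. With 2 libraries against 2 there are 6 splits, so an exact permutation test cannot give a p under 0.333. Adjusted p values here rest on a spread shared across genes or classes. Standard errors are the absolute log2 fold change divided by the square root of the test's F statistic. They are derived from the test, not fitted, and can be too small where a group held few UMIs.

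The genes named were set by a rule. In each class they are those past the threshold in which both libraries of 1 group lie above both of the other, up to 12 per direction in cardiomyocyte-like nuclei and up to 6 in each other class, by smallest adjusted p. Where fewer than 3 passed in a direction, the 3 smallest unadjusted p values of that direction are given as values. Predicted genes were counted but not named. From each list, up to 4 members past the threshold or otherwise up to 2 with the smallest p may be named.

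Besides the marker lists, 18 lists of genes were fixed: fatty acid oxidation, glycolysis and glucose uptake, nuclear-encoded respiratory chain, mitochondrially encoded, sarcomere and Z-disc, calcium handling and ion channels, fetal and stress response genes of cardiomyocytes, atrial cardiomyocyte, cell cycle, extracellular matrix and fibrosis, inflammatory cytokines and NF-kB, interferon response and antigen presentation, immediate early and heat shock, hypoxia and angiogenesis, imprinted genes, circadian clock, glucocorticoid-responsive, and DNA methylation and histone modifiers. Each list with at least 5 tested members was tested by camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists of a class. Camera with an estimated correlation and fry were alternatives. Fry tests whether the genes of a list move, on balance, in 1 direction, and does not compare them with other genes.

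Alternatives were doublets kept, a stricter nucleus filter (1000 UMIs, 500 genes, 2% mitochondrial), a class given to each nucleus by its highest marker score, genes centred within each library before clustering, Leiden resolution 2.0, each library left out in turn, the replicate number of the titles as a block, the DESeq2 1.42.0 Wald test, limma-voom, DESeq2 size factors in edgeR, TMM over classes for the shares, no low count filter, and counts thinned to the smallest total. Where a library was left out, its group kept 1 library, which is assumed to vary like the other group. After the data were seen, fits on the largest cardiomyocyte and fibroblast cluster, with the mixed endocardial cluster, and over all nuclei without adipocyte-like and mesothelial-like nuclei were added, as was a test of whether a change differs between cardiomyocyte-like nuclei and each other class. That test holds a term for each heart, so the 2 classes are compared within a heart, and it rests on 2 hearts per group.

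The fits were tested on simulated data with known changes. Of simulated changes of 4-fold, the edgeR fit recovered 98.5% in cardiomyocyte-like, 94% in endocardial-like, 98.5% in fibroblast-like, 86.6% in macrophage-like, 92.5% in pericyte-like, 83.6% in smooth muscle-like and 97% in vascular endothelial-like nuclei. Of changes of 2-fold it recovered between 29.9% (smooth muscle-like) and 73.1% (fibroblast-like). In each of these fits 200 genes were changed at once, and every gene was drawn at the trended spread for its level. Recovery may be lower where few genes change or where a gene varies more than the trend. For a simulated list moved by 1 on the log2 scale, camera with the preset correlation made the call, while camera with an estimated correlation (adjusted p = 0.16) and fry (adjusted p = 0.0622) did not. The preset correlation made 1 more call among the 26 lists, of fibroblast markers, of which 4 of 12 members belong to the moved list. Genes were drawn independently in this simulation, so it does not show how the tests behave for lists whose genes move together. The test of the difference between classes, run on pericyte- against cardiomyocyte-like nuclei drawn in the same way, recovered 81.8% of 4-fold and 25.8% of 2-fold differences. Simulated 4-fold rises in the number of nuclei of a class were recovered in 99% of cases, with calls in 6.17% of the other groups. Only endocardial- and smooth muscle-like nuclei were raised there, with 1 small fixed spread for all groups. The shares of the other groups fell as the totals grew, so 6.17% is not a rate of calls among unchanged shares. The adipocyte-like share varied more (1.63% with an SD of 0.644 with injured fathers), so these rates need not hold for it.

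Total counts were 29298446 and 40004944 UMIs in the libraries of injured fathers' offspring (replicates 1 and 2) and 38102388 and 21723461 in those of uninjured fathers' offspring. Intervals on shares of 1 library are 95% Wilson intervals. Ratios of gene counts are given with 95% exact binomial intervals where a group held 1 to 3 UMIs. Both cover counting error only.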

Results

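The data are single-nucleus RNA counts from 4 mouse hearts, each an injured heart of a male offspring taken 21 days after an injury at day 1 of life. The fathers had themselves been injured for 2 libraries (injured-father libraries 1 and 2) and had not for the other 2 (uninjured-father libraries 1 and 2). The comparison asks whether nuclei of an injured heart differ according to whether the father's heart had been injured. After filtering, 8187 and 9420 nuclei with 23298694 and 32408771 UMIs remained in the injured-father libraries, and 9389 and 6759 nuclei with 31325134 and 15521047 UMIs in the uninjured-father libraries. Median UMIs per nucleus were 2125, 2664.5, 2521 and 1856 in that order, so uninjured-father library 2 was the shallowest. Doublets were 10.5%, 11.0%, 9.88% and 15.3% of the nuclei that passed the filter. Haemoglobin transcripts stood at 759, 1199, 1739 and 775 CPM in spite of the sort against blood cells. Y-linked genes were at 483, 488, 459 and 436 CPM in the recorded males. Sftpc, a lung epithelial gene, had 1, 0, 0 and 1 UMIs, and Ucp1, a gene of brown fat cells, had 424, 47, 10 and 5.

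Adipocyte-like nuclei, which carry markers of fat cells such as Adipoq and Plin1, and mesothelial-like nuclei, which carry markers of the outer lining of the heart such as Msln and Upk3b, were larger shares of the hearts from injured fathers. Mesothelial-like nuclei made up 0.651% ± 0.0644 (SD, n = 2) against 0.0976% ± 0.0125 (SD, n = 2), a log2 fold change of 2.70 with a standard error of 0.22 and an adjusted p of 0.00558 (edgeR). Adipocyte-like nuclei made up 1.63% ± 0.644 against 0.148% ± 0.0623, a log2 fold change of 3.42 with a standard error of 0.50 and an adjusted p of 0.0312. Both shares were higher in 2 of 2 injured-father libraries than in either uninjured-father library. The counts behind them were small. Mesothelial-like nuclei numbered 57 and 57 against 10 and 6, and adipocyte-like nuclei 171 and 111 against 18 and 7. The share of adipocyte-like nuclei ran from 1.18% (Wilson interval 0.98 to 1.42) to 2.09% (1.80 to 2.42) with injured fathers and from 0.104% (0.0502 to 0.214) to 0.192% (0.121 to 0.303) with uninjured fathers.

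The other 12 groups of nuclei did not pass the threshold. Cardiomyocyte-like nuclei, the contracting muscle cells, made up 25.0% ± 2.55 with injured fathers and 30.9% ± 0.499 with uninjured fathers (log2 fold change -0.31, adjusted p = 0.302, edgeR). Vascular endothelial-like nuclei, from the lining of vessels, made up 23.0% ± 0.0176 against 19.8% ± 0.710 (adjusted p = 0.400, edgeR), and fibroblast-like nuclei 23.8% ± 1.86 against 25.6% ± 0.474 (adjusted p = 0.543, edgeR). Pericyte-like nuclei, from cells that wrap small vessels, made up 8.54% against 10.1% (adjusted p = 0.469, edgeR), and macrophage- or monocyte-like nuclei 4.43% against 4.07% (adjusted p = 0.525, edgeR). Endocardial-like nuclei, from the inner lining of the chambers, made up 3.95% against 2.68% (log2 fold change 0.56, adjusted p = 0.253, edgeR), and smooth muscle-like nuclei 1.15% against 1.69% (log2 fold change -0.55, adjusted p = 0.272, edgeR). T or NK lymphocyte-like nuclei made up 1.68% against 0.591% (log2 fold change 1.48, adjusted p = 0.302, edgeR) and B lymphocyte-like nuclei 2.52% against 1.55% (adjusted p = 0.479, edgeR). Lymphatic endothelial-like nuclei made up 1.03% against 0.822% (adjusted p = 0.525, edgeR), Schwann- or glial-like nuclei 0.643% against 0.718% (adjusted p = 0.525, edgeR), and unnamed nuclei 1.90% against 1.26% (adjusted p = 0.479, edgeR). The call of the adipocyte-like share ended without any 1 library (adjusted p 0.128 and 0.120 without injured-father library 1 and 2, 0.129 and 0.324 without uninjured-father library 1 and 2), and so did that of the mesothelial-like share (0.0687, 0.0588, 0.0755 and 0.124 in the same order). Both calls also ended when each nucleus was classed by its marker score (log2 fold change 1.76 and adjusted p 0.0966 for adipocyte-like, 0.73 and 0.126 for mesothelial-like nuclei), and the adipocyte-like call ended with doublets kept (0.0543).

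**Figure D1:**
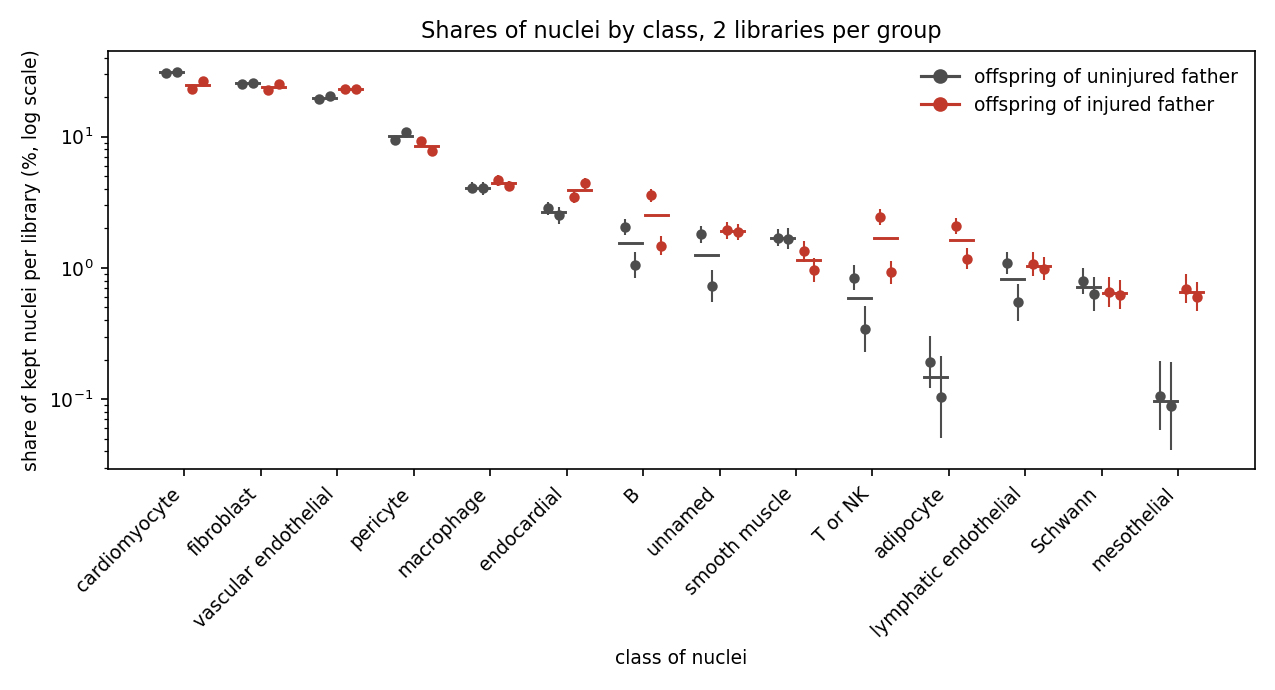
Share of kept nuclei in each class (vertical axis, percent, log scale) for each library, with 95% Wilson intervals as bars, dots for libraries and short lines for group means (n = 2 libraries per group). Mesothelial-like nuclei sit at 0.605% and 0.696% with injured fathers and at 0.0888% and 0.107% with uninjured fathers.

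The genes called in the most classes were Slc15a2 and Camk1d. Slc15a2 (ENSMUSG00000022899, chromosome 16, 36750177 to 36784962 on GRCm38) encodes a peptide transporter of the cell membrane. It was close to absent with uninjured fathers, and rose with injured fathers in cardiomyocyte-, fibroblast-, pericyte- and macrophage-like nuclei. The log2 fold change was 5.67 in cardiomyocyte-like nuclei. In the others, with 2 or 3 UMIs in the uninjured-father libraries, the ratios of counts were 50.1, 35.9 and 13.7. Camk1d (ENSMUSG00000039145, chromosome 2, 5293457 to 5714515) encodes a calcium-dependent protein kinase, and rose in fibroblast-, pericyte- and macrophage-like nuclei by 1.18, 1.13 and 0.83. In the other 4 tested classes Camk1d had log2 fold changes between 0.96 and 1.19 that did not pass the threshold. Over all libraries its level ran from 2719 CPM in cardiomyocyte-like to 7966 CPM in macrophage-like nuclei among the tested classes. It was highest in T or NK lymphocyte-like nuclei, at 9837 CPM. Lars2, Cdk8 and Cmss1, chosen after their values were seen, also had positive log2 fold changes in 7 of 7 classes, between 0.52 and 0.89, 0.22 and 0.63, and 0.12 and 0.43, and none of the 3 was called in a class (edgeR). Both injured-father libraries lay above both uninjured-father libraries in 7, 3 and 1 of these classes. What lies behind a rise shared by all tested classes, for Camk1d and for these genes, was not tested.

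**Figure D2:**
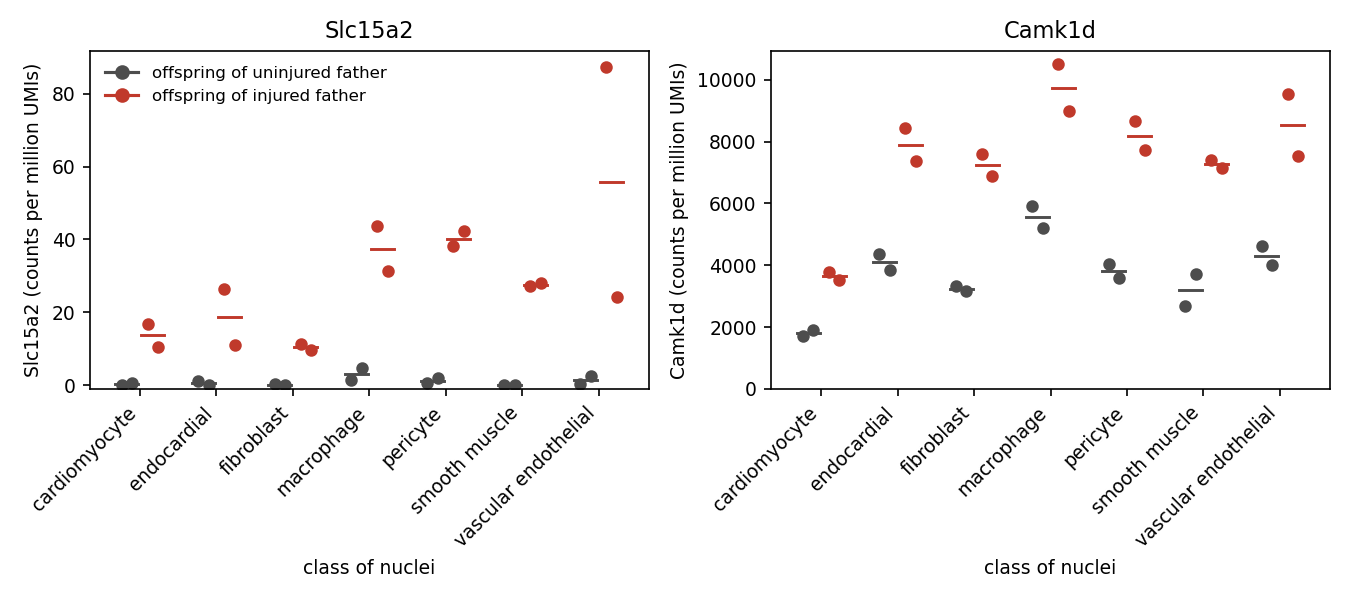
Level of Slc15a2 (left) and Camk1d (right) in each tested class (vertical axis, CPM of the class total without TMM scaling), with a dot per library and a short line per group mean (n = 2 libraries per group). Slc15a2 lies near 0 in the uninjured-father libraries, and Camk1d is higher in both injured-father libraries in each of the 7 classes.

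In cardiomyocyte-like nuclei 2 genes rose and 0 fell among 12508 tested. Slc15a2 stood at 13.8 CPM with injured and 0.317 CPM with uninjured fathers (166 and 154 against 2 and 4 UMIs, standard error 0.49, adjusted p = 0.00732, edgeR). Mbp (ENSMUSG00000041607, chromosome 18, 82475146 to 82585637), known for encoding myelin basic protein, rose from 2.82 to 14.0 CPM (log2 fold change 2.25, standard error 0.26, adjusted p = 0.0344, edgeR). Its level was highest in mesothelial-like nuclei, at 442 CPM. Camk1d stood at 3675 against 1812 CPM (log2 fold change 1.02, adjusted p = 0.0811, edgeR). Tcap, a protein of the sarcomere's Z-disc, had -0.77 (adjusted p = 0.278, edgeR), Cdh6 -1.62 (adjusted p = 0.278, edgeR) and Dcp1b -0.78 (adjusted p = 0.323, edgeR). A p under 0.05 before adjustment was found for 505 genes, and the groups did not overlap for 30.5% of genes, where chance gives 33.3%. The count was 0 with limma-voom (491 genes with an unadjusted p under 0.05), and 1 by marker score, at resolution 2.0 and in the largest cluster. Without injured-father library 1 or 2 the count was 42 or 38, and without uninjured-father library 1 or 2 it was 6 or 1. Slc15a2 was not called without uninjured-father library 1 (log2 fold change 4.71, adjusted p = 0.0597, edgeR) and was called without uninjured-father library 2, where Mbp was not called (2.01, adjusted p = 0.119, edgeR).

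Gene groups of cardiomyocyte-like nuclei were read from the fixed lists, and 9 of 27 were called by camera. Atrial genes rose as a group, with 8 of 8 members positive (median log2 fold change 1.12) and 0 members called alone, or 1 when adjusted over the list alone (adjusted p = 0.633 with an estimated correlation). Dkk3 had 1.76 and Stard10 0.81 in this list. The cluster led by atrial genes made up 9.28% and 12.2% of cardiomyocyte-like nuclei with injured fathers and 6.45% and 2.27% with uninjured fathers. The atrial call with the preset correlation also held in the largest cardiomyocyte cluster alone, which leaves that cluster out. Fatty acid oxidation rose as a group, with 23 of 27 members positive (median 0.22), 0 called over all genes and 1 adjusted over the list alone (adjusted p = 0.633 with an estimated correlation). Ucp3, a mitochondrial carrier, had 0.96 and Slc25a20, which carries acylcarnitine into mitochondria, had 0.61. The sarcomere and Z-disc list fell, with 26 of 30 members negative (median -0.19), 0 called and 1 adjusted over the list alone (adjusted p = 0.633 with an estimated correlation). Interferon response and antigen presentation (19 of 23 positive, median 0.28, H2-K1 at 0.77), hypoxia and angiogenesis (17 of 24 positive, 0.14, Adm at 2.04) and inflammatory cytokines (6 of 9 positive, 0.13, Il1r1 at 0.90) rose, with 0 members called and 0, 1 and 1 adjusted over the list alone (adjusted p = 0.633 with an estimated correlation for each). Among markers of other cell types, those of vascular endothelium (11 of 11 positive, median 0.22) and endocardium (3 of 6, 0.19) rose and those of smooth muscle fell (5 of 6 negative, -0.55), with 0 members called and 0, 2 and 0 adjusted over the list alone (adjusted p = 0.633, 0.802 and 0.802 with an estimated correlation). The hypoxia list and the vascular endothelial markers share Kdr, Flt1 and Tek, so their calls are not separate evidence. None of the 9 calls held with an estimated correlation (smallest adjusted p = 0.633 with an estimated correlation) or with fry (smallest adjusted p = 0.424). The atrial call held without each library, while those of fatty acid oxidation, interferon response, hypoxia, inflammatory cytokines, vascular endothelial and smooth muscle markers ended without uninjured-father library 1, those of the sarcomere and inflammatory lists without injured-father library 1, those of endocardial and smooth muscle markers without injured-father library 2, and that of endocardial markers without uninjured-father library 2. The call of endocardial markers also ended with doublets kept, with the stricter nucleus filter, by marker score and in the largest cluster, that of vascular endothelial markers by marker score, and that of inflammatory cytokines in the largest cluster.

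In fibroblast-like nuclei, the cells that make much of the heart's matrix, 4 genes rose and 0 fell among 12402 tested. Slc15a2 had 53 and 66 UMIs with injured and 2 and 0 with uninjured fathers, a ratio of 50.1 with a counting interval of 13.6 to 418 (adjusted p = 0.00495, edgeR). Camk1d rose from 3235 to 7305 CPM (log2 fold change 1.18, standard error 0.15, adjusted p = 0.0188, edgeR). Sntg1 (ENSMUSG00000025909), which encodes a syntrophin, rose from 118 to 248 CPM (log2 fold change 1.07, standard error 0.14, adjusted p = 0.0188, edgeR). Sntg1 leads a cluster that made up 31.9% and 38.0% of fibroblast-like nuclei with injured fathers and 28.6% and 23.1% with uninjured fathers. In the largest fibroblast cluster alone, which is another cluster, 2 of the 4 calls remained. Car3 (ENSMUSG00000027559, chromosome 3, 14863512 to 14872523), a carbonic anhydrase, rose from 0.629 to 9.75 CPM (log2 fold change 3.76, standard error 0.53, adjusted p = 0.0351, edgeR), and stood at 2007 CPM in adipocyte-like nuclei. Acta2, the smooth muscle actin, had -0.91 (adjusted p = 0.241, edgeR), Hs3st3a1 -0.70 (0.328) and Spon1 -0.57 (0.892). Before adjustment 386 genes had a p under 0.05, and groups did not overlap for 29.5% of genes, where chance gives 33.3%. The count was 139 and 42 without injured-father library 1 and 2, and 2 and 1 without uninjured-father library 1 and 2. Camk1d, Sntg1 and Car3 were not called without either uninjured-father library (adjusted p 0.0759, 0.0702 and 0.335 without library 1, and 0.155, 0.206 and 0.206 without library 2, edgeR). Slc15a2 was called without each library, but without uninjured-father library 1 the remaining uninjured-father library had 0 UMIs, so no fold is given.

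Of 27 lists tested in fibroblast-like nuclei 10 were called by camera. Immediate early and heat shock genes, switched on within minutes of a stimulus, rose as a group, with 19 of 24 positive (median 0.32), 0 members called and 2 adjusted over the list alone (adjusted p = 0.616 with an estimated correlation). Nr4a3 had 1.70 and Junb 0.97. Inflammatory cytokines and NF-kB rose, with 13 of 15 positive (0.18) and Nfkb2 at 0.82 and Icam1 at 0.85 (adjusted p = 0.616 with an estimated correlation). Extracellular matrix and fibrosis fell, with 29 of 41 negative (-0.08), 0 members called and 1 adjusted over the list alone, which was Acta2, and Col8a1 had -0.43 (adjusted p = 0.616 with an estimated correlation). The sarcomere list (26 of 29 negative, -0.24), cardiomyocyte markers (12 of 12 negative, -0.27), smooth muscle markers (5 of 6 negative, -0.34) and mitochondrially encoded genes (10 of 13 negative, -0.21) fell (adjusted p = 0.616 with an estimated correlation for each). Atrial genes (6 of 6 positive, 0.70), endocardial markers (6 of 6, 0.40) and vascular endothelial markers (10 of 11, 0.18) rose (adjusted p = 0.616 with an estimated correlation for each). The cluster of cardiomyocyte-like nuclei led by atrial genes made up 2.15% and 3.26% of all nuclei with injured fathers and 1.97% and 0.71% with uninjured fathers. In these lists 0 members were called over all genes, and 1 each of the smooth muscle and endocardial markers adjusted over the list alone. None of the 10 calls held with an estimated correlation (smallest adjusted p = 0.616 with an estimated correlation) or with fry (smallest adjusted p = 0.641). The atrial call held without each library, while others ended without injured-father library 1 (cardiomyocyte and smooth muscle markers, sarcomere, inflammatory), injured-father library 2 (vascular endothelial and endocardial markers, mitochondrially encoded, matrix), uninjured-father library 1 (vascular endothelial and smooth muscle markers, mitochondrially encoded, inflammatory, immediate early) or uninjured-father library 2 (cardiomyocyte and endocardial markers, matrix), and mitochondrially encoded genes turned direction with the stricter nucleus filter, where the call of smooth muscle markers ended, as it and that of vascular endothelial markers did by marker score.

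In pericyte-like nuclei 3 genes rose and 0 fell among 10019 tested. Slc15a2 had 51 and 66 UMIs with injured fathers and 3 in both uninjured-father libraries together, a ratio of 35.9 with a counting interval of 12 to 177 (adjusted p = 3.17e-09, edgeR). Camk1d rose from 3821 to 8375 CPM (log2 fold change 1.13, standard error 0.14, adjusted p = 2.76e-06, edgeR). Pparg (ENSMUSG00000000440), a nuclear receptor that drives fat cell formation, rose from 52.6 to 108 CPM (log2 fold change 1.04, standard error 0.18, adjusted p = 0.00272, edgeR), and stood at 3562 CPM in adipocyte-like nuclei. As3mt had -0.98, Aga -1.38 and Itga9 -0.58, with adjusted p between 0.790 and 0.999 (edgeR). Only the sarcomere list was called of 23, lower, with 25 of 29 members negative (median -0.19), 0 called alone and 0 adjusted over the list alone (adjusted p = 0.814 with an estimated correlation, 0.812 with fry). Cardiomyocyte markers were negative in 10 of 12 beside it (median -0.17, adjusted p = 0.370, camera). Before adjustment 423 genes had a p under 0.05, and groups did not overlap for 31.8% of genes, where chance gives 33.3%. Without 1 library the count was 18 and 9 (injured-father 1 and 2) and 23 and 7 (uninjured-father 1 and 2), and the sarcomere call ended without injured-father library 1 or uninjured-father library 2 and with the stricter nucleus filter. All 3 genes were called without each library.

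In macrophage- or monocyte-like nuclei 5 genes rose and 3 fell among 8247 tested. Camk1d rose from 5708 to 10120 CPM (log2 fold change 0.83, standard error 0.14, adjusted p = 0.0437, edgeR), and Cadm1 (ENSMUSG00000032076), an adhesion molecule, from 312 to 620 CPM (0.98, standard error 0.17, adjusted p = 0.0437, edgeR). Slc15a2 had 30 and 25 UMIs with injured and 3 in all with uninjured fathers, a ratio of 13.7 with a counting interval of 4.45 to 68.4 (adjusted p = 0.0437, edgeR). Npr3 (ENSMUSG00000022206), the natriuretic peptide clearance receptor, rose by 2.24 and Csmd1 (ENSMUSG00000060924) by 1.96 (adjusted p = 0.0466 for each, edgeR). Plcb4 (ENSMUSG00000039943), a phospholipase C, fell by 1.05, Ccdc85a (ENSMUSG00000032878) fell by 1.25 and Tshz2 (ENSMUSG00000047907) fell by 0.93 (adjusted p = 0.0466, 0.0466 and 0.0473, edgeR). Each of these genes had its highest level in another class, such as Npr3 in endocardial-like nuclei (3020 CPM), Csmd1 and Cadm1 in Schwann-like nuclei (18700 and 1366), and Plcb4 and Ccdc85a in vascular endothelial-like nuclei (3589 and 1749). Before adjustment 565 genes had a p under 0.05, and groups did not overlap for 35.6% of genes, where chance gives 33.3%. The count was 0 with doublets kept (edgeR, 423 genes with an unadjusted p under 0.05), 1 with DESeq2, 5 with limma-voom, 67 and 24 without injured-father library 1 and 2, and 39 and 50 without uninjured-father library 1 and 2. Without injured-father library 2, Cadm1, Plcb4, Ccdc85a and Tshz2 were not called (adjusted p 0.0580, 0.123, 0.0633 and 0.153, edgeR), nor was Tshz2 without uninjured-father library 1 (0.0758), and Slc15a2 was called without each library.

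Of 23 lists in macrophage- or monocyte-like nuclei 8 were called. Extracellular matrix and fibrosis fell, with 24 of 25 members negative (median -0.63), 0 called over all genes and 5 adjusted over the list alone (adjusted p = 0.677 with an estimated correlation). Col15a1 had -0.98 and Col8a1 -2.05 in it. Vascular endothelial markers fell, with 11 of 11 negative (-0.60), 0 called and 8 adjusted over the list alone (adjusted p = 0.839 with an estimated correlation), but turned direction with doublets kept, where the calls of hypoxia and interferon response ended. Hypoxia and angiogenesis fell, with 12 of 16 negative (-0.45), 0 called and 6 adjusted over the list alone (adjusted p = 0.677 with an estimated correlation). Egln1, an oxygen sensor, had -0.78 and Tie1, an endothelial receptor, -1.26. Kdr, Flt1 and Tek are in both this list and the vascular endothelial markers, so these calls are not separate evidence. Fibroblast markers (10 of 11 negative, -0.58), cardiomyocyte markers (11 of 12, -0.28) and the sarcomere list (23 of 27, -0.31) fell, with 0 members called or adjusted over the list alone (adjusted p = 0.990 with an estimated correlation for each). Interferon response and antigen presentation rose, with 19 of 25 positive (0.24), 0 called and H2-Aa at 0.99, and endocardial markers rose, with 5 of 5 positive (0.77) and Npr3 called (adjusted p = 0.990 and 0.677 with an estimated correlation). None of the 8 calls held with an estimated correlation (smallest adjusted p = 0.677 with an estimated correlation) or with fry (smallest adjusted p = 0.462). The calls of matrix genes and vascular endothelial markers held without each library, while those of fibroblast, cardiomyocyte and sarcomere genes ended without injured-father library 1 or uninjured-father library 1, that of hypoxia without uninjured-father library 1, that of interferon response without injured-father library 2 or uninjured-father library 1, and that of endocardial markers without injured-father library 1, and by marker score those of cardiomyocyte, endocardial, sarcomere and interferon genes ended, as did that of cardiomyocyte markers with the stricter nucleus filter.

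In endocardial-like nuclei 5 genes rose and 1 fell among 8216 tested. Col25a1 (ENSMUSG00000058897), a membrane collagen, rose from 174 to 456 CPM (log2 fold change 1.36, standard error 0.18, adjusted p = 2.90e-05, edgeR). Pde10a (ENSMUSG00000023868), a phosphodiesterase, rose from 96.2 to 314 CPM (1.62, standard error 0.21, adjusted p = 2.90e-05, edgeR). Cdh4 (ENSMUSG00000000305), a cadherin, rose by 1.67, Fgf12 (ENSMUSG00000022523) by 1.75 and Nmnat2 (ENSMUSG00000042751), an enzyme of NAD synthesis, by 1.66 (adjusted p = 0.00461, 0.00531 and 0.0405, edgeR). Ptprt (ENSMUSG00000053141), a receptor phosphatase, fell by 1.4 (adjusted p = 0.0128, edgeR). Col4a4 had -0.75 (adjusted p = 0.0677, edgeR) and Pdgfrb, the receptor that marks pericytes, -1.18 (0.0796). Fgf12 stood at 1258 CPM in cardiomyocyte-like nuclei, where it leads the cluster with atrial genes, and Pde10a and Ptprt were highest in mesothelial-like nuclei (707 and 119 CPM). Of 21 lists 3 were called, all lower: cardiomyocyte markers (12 of 12 negative, median -0.26), the sarcomere list (22 of 26, -0.25) and pericyte markers (5 of 5, -0.78), with 0 members called and 0, 0 and 3 adjusted over the list alone. None held with an estimated correlation (smallest adjusted p = 0.820 with an estimated correlation) or with fry (smallest 0.487), all 3 ended without injured-father library 1 or uninjured-father library 1, the cardiomyocyte marker call also ended without uninjured-father library 2, and cardiomyocyte markers turned direction by marker score, where the sarcomere call ended, and both calls ended with the stricter nucleus filter. Before adjustment 426 genes had a p under 0.05, and groups did not overlap for 32.8%, where chance gives 33.3%. The count was 3 when counts were thinned and 1 with the mixed endocardial cluster, where Col25a1 and Pde10a were thus not both called. The count was 24 and 25 without injured-father library 1 and 2, 23 and 37 without uninjured-father library 1 and 2, 0 by marker score (edgeR, 412 genes with an unadjusted p under 0.05), and 3 with DESeq2. Col25a1 and Pde10a were called without each library, but Cdh4 was not without injured-father library 2 (adjusted p = 0.0597) or uninjured-father library 1 (0.0617), Fgf12 not without injured-father library 2 (0.0889) and at 2.40 without uninjured-father library 1, Nmnat2 not without injured-father library 1 (0.196), and Ptprt not without uninjured-father library 1 (0.438).

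In vascular endothelial-like nuclei 1 gene, Car3, rose and 0 fell among 11323 tested. Car3 rose from 0.758 to 15.4 CPM (log2 fold change 4.03, standard error 0.53, adjusted p = 0.0427, edgeR), with 43 and 74 UMIs against 5 and 0. Slc15a2 had 275 and 108 UMIs with injured and 1 and 5 with uninjured fathers, but its adjusted p was 0.910 (edgeR, log2 fold change 5.57). Camk1d stood at 8689 against 4277 CPM (log2 fold change 1.02, adjusted p = 0.0517, edgeR) and Prkar2b, whose level was highest in adipocyte-like nuclei at 2135 CPM, at 14.7 against 3.23 (2.05, adjusted p = 0.329, edgeR). Crip1 had -1.03 and Alpl -0.98 (adjusted p = 0.149 and 0.753, edgeR). Of 27 lists 4 were called. Nuclear-encoded respiratory chain genes fell, with 44 of 50 negative (median -0.17), 0 called and 0 adjusted over the list alone, and with Ndufa13 at -0.48 and Cox4i1 at -0.38 (adjusted p = 0.877 with an estimated correlation). The sarcomere list (26 of 29 negative, -0.21) and smooth muscle markers (5 of 6, -0.62) fell and atrial genes rose (6 of 6 positive, 0.98, Bmp10 at 4.45 and Myl7 at 1.11), with 0 members called and 0, 0 and 2 adjusted over the list alone (adjusted p = 0.877 with an estimated correlation for each). Beside these, the cluster of cardiomyocyte-like nuclei led by atrial genes made up 2.15% and 3.26% of all nuclei with injured and 1.97% and 0.71% with uninjured fathers, and cardiomyocyte markers were negative in 9 of 12 (median -0.16, adjusted p = 0.102, camera). None held with an estimated correlation (smallest adjusted p = 0.877 with an estimated correlation) or with fry (smallest 0.858), and the respiratory chain call ended without injured-father library 1 or uninjured-father library 2, the sarcomere call without injured-father library 1 or uninjured-father library 1, and the smooth muscle call without injured-father library 2 or uninjured-father library 1, with doublets kept and with the stricter nucleus filter. Before adjustment 602 genes had a p under 0.05, and groups did not overlap for 34.5%, where chance gives 33.3%. The count was 49 and 30 without injured-father library 1 and 2, 83 and 10 without uninjured-father library 1 and 2, and 0 with doublets kept (edgeR, 609 genes with an unadjusted p under 0.05). Car3 was called without each library, with a log2 fold change of 3.33 without uninjured-father library 2, and without library 1 the remaining uninjured-father library had 0 UMIs, so no fold is given.

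In smooth muscle-like nuclei no change passed the threshold. Eln, which encodes elastin, the stretchable fibre of vessel walls, stood at 1041 with injured and 3095 CPM with uninjured fathers (log2 fold change -1.56, standard error 0.33, adjusted p = 0.296, edgeR). Camk1d had 1.19, Negr1 1.81 and Nkain2 1.59 (adjusted p = 0.112 for each, edgeR), Fmo2 -1.02 (0.792) and Postn, a matrix protein of wound healing, -0.99 (0.818). Negr1 was highest in adipocyte-like and Nkain2 in Schwann-like nuclei (2034 and 5215 CPM). Of 4591 genes 0 were called by edgeR, 178 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 1 each, and groups did not overlap for 32.5% (33.3% by chance). Of 19 lists 0 were called by camera (smallest adjusted p = 0.632 with an estimated correlation, 0.359 with fry), with 3 of 28 matrix genes lower when adjusted over the list alone. The count was 38 and 6 without injured-father library 1 and 2 and 2 and 2 without uninjured-father library 1 and 2.

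**Figure D3:**
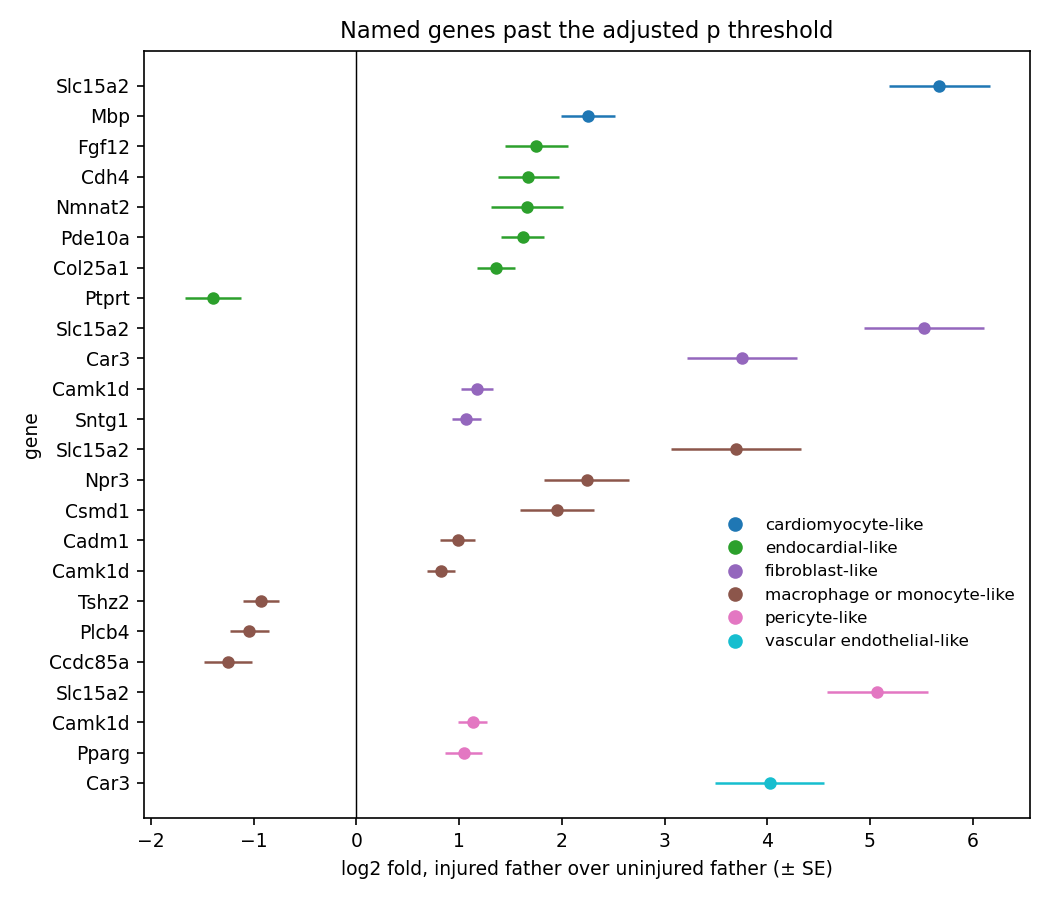
Log2 fold change of injured over uninjured father (horizontal axis) with the standard error derived from the test, for each gene past the threshold in a class (vertical axis, colour for the class), from edgeR with 2 libraries per group. The bars can be too short where a group held few UMIs, as for Slc15a2. Slc15a2 lies between 3.70 and 5.67 in the 4 classes that called it.

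**Figure D4:**
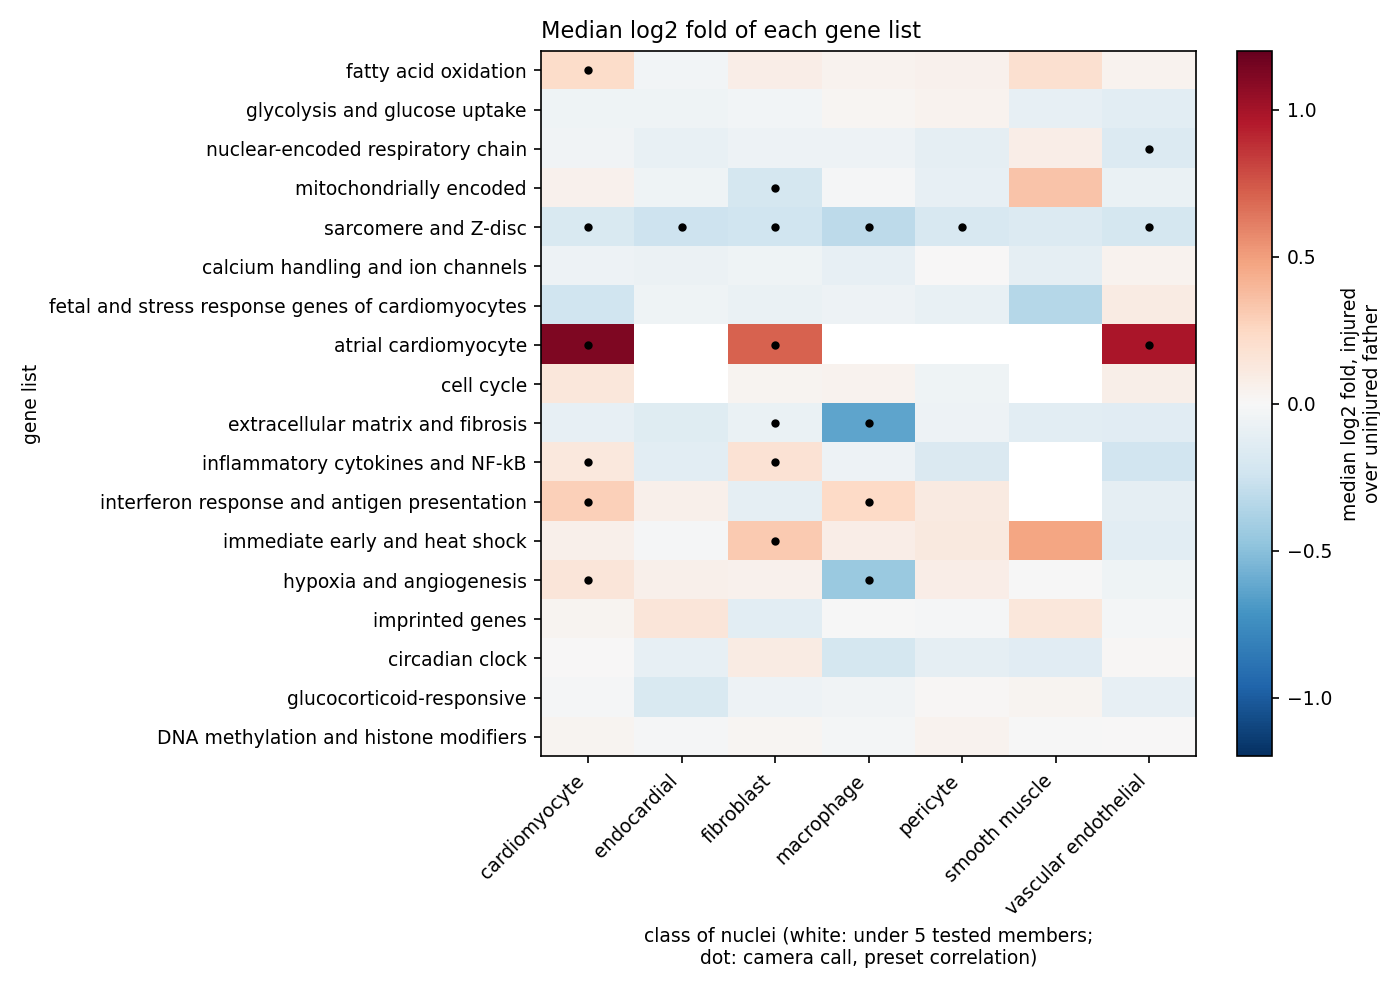
Median log2 fold change of each of the 18 pathway lists (vertical axis) in each tested class (horizontal axis), as colour, with dots where camera made a call with the preset correlation and white where under 5 members were tested (n = 2 libraries per group). The sarcomere and Z-disc list was called lower in 6 of the 7 classes, and none of the calls shown held with an estimated correlation or with fry.

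Summed over all nuclei of a library, 29 genes rose and 3 fell among 14879 tested, and markers of fat cells and of the outer lining led the list. The genes named here from all nuclei were chosen after their values were seen. Plin1, which coats fat droplets, rose by 3.21 on the log2 scale, Cidec by 3.73, Cfd by 3.80 and Adipoq by 5.13 (adjusted p = 0.00228, 0.00308, 0.00533 and 0.00772, edgeR). Muc16 rose by 3.56 (adjusted p = 0.00247, edgeR). The 3 genes that fell were Dhrs7c (-0.86, adjusted p = 0.0456), Tcap (-0.82, adjusted p = 0.0495) and Spp1 (-3.49, adjusted p = 0.0495, with 2 and 4 against 42 and 17 UMIs, edgeR). Adipocyte markers rose with 7 of 7 members positive (median 3.73, 4 called, 6 adjusted over the list alone), and mesothelial markers with 7 of 7 (3.56, 5 called, 7 adjusted over the list alone). Their calls were lost with an estimated correlation (adjusted p = 0.225 with an estimated correlation) and held with fry (adjusted p = 0.0358). The count was 0 without adipocyte-like and mesothelial-like nuclei, a fit added after the data were seen (edgeR, 853 genes with an unadjusted p under 0.05). It was 267 and 506 without injured-father library 1 and 2, 0 without uninjured-father library 1 or 2 (1273 and 617 genes with an unadjusted p under 0.05), and 95 with DESeq2.

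Other lists moved over all nuclei, where a share of nuclei and a level in them cannot be separated. The sarcomere and Z-disc list fell with 29 of 30 negative (median -0.36, Tcap called, 7 adjusted over the list alone, adjusted p = 0.620 with an estimated correlation). Cardiomyocyte (12 of 12 negative, -0.38), smooth muscle (7 of 7, -0.62) and pericyte markers (8 of 8, -0.21), calcium handling and ion channels (22 of 28, -0.20), fetal and stress response genes (14 of 20, -0.37) and the nuclear-encoded respiratory chain (44 of 50, -0.13) fell (adjusted p between 0.620 and 0.783 with an estimated correlation). T or NK lymphocyte markers (7 of 7 positive, 1.51), atrial genes (8 of 8, 0.82), vascular endothelial markers (11 of 11, 0.20), fatty acid oxidation (18 of 27, 0.12), interferon response (28 of 40, 0.11), immediate early genes (22 of 28, 0.13) and hypoxia (23 of 28, 0.17) rose (adjusted p between 0.620 and 0.819 with an estimated correlation). In these 13 lists only interferon response had a member called over all genes. None of these calls, nor that of the sarcomere list, held with an estimated correlation (smallest adjusted p = 0.620 with an estimated correlation) or with fry (smallest adjusted p = 0.483). Markers of neutrophils (median -0.28, adjusted p = 0.527), B lymphocytes (0.59, 0.0520) and Schwann or glial cells (-0.05, 0.734) were not called. Skeletal muscle and lung epithelial markers had too few members above the count filter for a test.

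Within the 7 classes, 16 of the 27 lists that could be tested in a class were called in at least 1, and the sarcomere and Z-disc list was called lower in 6. None of the calls held with an estimated correlation (smallest adjusted p = 0.616 with an estimated correlation) or with fry. Cardiomyocyte markers fell beside the sarcomere list in fibroblast-like (12 of 12 negative), endocardial-like (12 of 12) and macrophage-like nuclei (11 of 12). They were negative without a call in cardiomyocyte-like (10 of 12), pericyte-like (10 of 12) and vascular endothelial-like nuclei (9 of 12). Both lists hold Ttn, Myh6, Myl2, Mybpc3, Actc1, Tnnt2 and Tnni3, so they are not separate evidence. Likewise, the hypoxia list and the vascular endothelial markers share Kdr, Flt1 and Tek. The matrix list and the fibroblast markers share Col1a1, Col1a2, Col3a1 and Lum. By the plan, markers of another class measure free RNA and mixed nuclei. Cardiomyocyte-like nuclei made up 25.0% with injured and 30.9% with uninjured fathers, and the source of these transcripts in other classes was not tested. The other 11 lists were called in none. Their smallest adjusted p over the classes was 0.0519 for imprinted genes, 0.102 for erythroid markers, 0.142 for both macrophage or monocyte markers and fetal and stress response genes, 0.169 for glucocorticoid-responsive genes, 0.279 for cell cycle, 0.348 for lymphatic endothelial markers, 0.353 for calcium handling and ion channels, 0.355 for glycolysis and glucose uptake, 0.362 for DNA methylation and histone modifiers, and 0.387 for the circadian clock (camera).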

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

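The tests of depth for Slc15a2, of adipocyte genes low in other classes, of the identity of adipocyte-like nuclei and of attached tissue, and all comparisons of a change between classes, were chosen only after the results were seen.

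Slc15a2 had 320 UMIs in cardiomyocyte-like nuclei with injured fathers and 6 with uninjured fathers, and was present in other tested classes of both injured-father libraries. Against free RNA from vascular endothelial-like nuclei, its level relative to these nuclei lay above that of every vascular endothelial marker in 7 of 10 sums, or 6 by the lower bound of counting. Against unequal depth, 3 of the 4 classes kept the call after thinning, and macrophage-like nuclei gave no value. A chromosome segment of another strain may still be carried by 1 group of families: 4 neighbouring gene tests of 119 had an unadjusted p under 0.05, where 5.45 are given by the share over all genes (hypergeometric p = 0.799, exact), and a segment that changes Slc15a2 alone cannot be told apart from the father's injury. An effect of the father's injury stays open and untested, since the fathers and litters are not given in the sources used here.

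Car3 was higher in fibroblast- and vascular endothelial-like nuclei of the injured-father libraries, and free RNA from the more numerous adipocyte-like nuclei may account for it. The test planned first summed 50 other adipocyte-led genes, which were higher in both injured-father libraries in 3 of 7 classes, a count that its prediction had set against free RNA. It was set aside after that count was seen, because these genes stood at 1788 to 6463 CPM in the uninjured-father libraries, and the addition could be seen in 4 classes, 3 of them higher. A second list was chosen after that result, of 34 genes at least 50 times higher in adipocyte-like nuclei. It was higher in 6 of 7 classes, and leads of 20 and 100 gave 6 and 7. The first version looked at, the 50 of highest level at a lead of 20 (49 without called genes), gave 5. The 34 genes rose by 52.95 CPM in fibroblast-like and 69.5 in vascular endothelial-like nuclei, where the Car3 difference would bring 53.18 and 85.03. In smooth muscle-like nuclei they rose by 37.13, where it would bring -23.88. These sizes go with free RNA in the 2 classes that called Car3. The versions together do not settle whether free RNA is the source. Against 2 nuclei in 1 droplet, 96.1% of nuclei of the tested classes with a Car3 UMI had exactly 1 (421 of 438), against 18.5% of adipocyte-like nuclei, and an effect of the father's injury on these classes stays open.

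Adipocyte-like and mesothelial-like nuclei were larger shares in both injured-father libraries. Against nuclei of other kinds counted as adipocyte-like, the adipocyte marker share of UMIs in these nuclei was 1.31 times as high with injured fathers. More tissue left attached to the heart at dissection may account for the shares: of 4 other kinds of nuclei, 2 were larger in both injured-father libraries, T or NK lymphocyte-like nuclei and the cluster led by atrial genes (2.15% and 3.26% against 1.97% and 0.71% of nuclei). How much tissue was left cannot be told apart from the father's injury with these 4 hearts, and an effect of the injury stays open and untested.

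The change between fathers was tested for a difference between cardiomyocyte-like nuclei and each other class, and the genes named in the next sentences passed that test. Tspan2, a gene chosen after its values were seen, had a log2 fold change of 2.38 in cardiomyocyte-like nuclei (adjusted p = 0.0810, edgeR, 61 and 81 against 20 and 7 UMIs). In endocardial-like nuclei 4 genes differed, Tspan2 (-2.43), Eps8 (-1.07), Sox5 (-1.06) and Epha4 (-1.23), where each value is the log2 fold change there minus that in cardiomyocyte-like nuclei. In macrophage-like nuclei 18 genes differed, among them Tshz2 (-1.2), Plcb4 (-1.22), Cadm1 (0.96) and Mbp (-1.82). In pericyte-like nuclei 6 differed (Irag1 -1.13, Daam2 -1.06, Ror2 -1.05, Cyria -0.97, Eps8 -0.92 and Tspan2 -2.38). In smooth muscle-like nuclei 7 differed, among them Eln (-1.64), Cdh6 (1.75) and Nkain2 (1.56), and in vascular endothelial-like nuclei 1 differed, Tspan2 (-2.47). In fibroblast-like nuclei 0 genes differed (edgeR, 580 of 13301 with an unadjusted p under 0.05).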

How the results depend on the processing

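Fits on the largest cluster, with the mixed endocardial cluster, and over all nuclei without adipocyte-like and mesothelial-like nuclei were chosen after seeing the data. Of the values of named genes under alternatives, 194 kept direction and side of the threshold, 45 kept direction but not the call and 0 reversed. Of those of the named classes whose share was not called, 127 were the same, 3 reversed and 2 became calls. Both called shares lost their call under several alternatives, given with their values in the paragraph on shares. The cause of the changes below was not tested, except that a left-out library leaves fewer samples. The smallest library limits depth, and Slc15a2 in macrophage-like nuclei gave no value after thinning.

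In cardiomyocyte-like nuclei the count of 2 genes became 1 by marker score, at resolution 2.0 and in the largest cluster, 20 with DESeq2, 0 with limma-voom (491 genes with an unadjusted p under 0.05), 137 with no low count filter, and 1 to 42 without 1 library. In endocardial-like nuclei 6 became 19 with the stricter filter, 0 by marker score (412), 3 with DESeq2, 19 with no filter, 3 when thinned, 1 with the mixed cluster, and 23 to 37 without 1 library. In fibroblast-like nuclei 4 became 23 with no filter, 2 in the largest cluster, and 1 to 139 without 1 library. In macrophage-like nuclei 8 became 0 with doublets kept (423), 3 by marker score, 1 with DESeq2, 5 with limma-voom, 58 with no filter, 5 when thinned, and 24 to 67 without 1 library. In pericyte-like nuclei 3 became 7 by marker score, 5 with limma-voom, 12 with no filter, and 7 to 23 without 1 library. In smooth muscle-like nuclei 0 (178) became 1 with DESeq2 and limma-voom, 6 with no filter, and 2 to 38 without 1 library. In vascular endothelial-like nuclei 1 became 0 with doublets kept (609), 2 at resolution 2.0, with DESeq2 and when thinned, 34 with no filter, and 10 to 83 without 1 library. Over all nuclei 32 became 95 with DESeq2, 0 without adipocyte-like and mesothelial-like nuclei (853), and 0 to 506 without 1 library. The 35 list calls became 0 with an estimated correlation and with fry. Both of these tests missed a simulated moved list, while the preset correlation called that list and also fibroblast markers, which share 4 of 12 members with it. That simulation drew genes independently, so it cannot tell which test is right where genes move together. In cardiomyocyte-like nuclei the estimated correlations of the called lists ran from -0.11 (inflammatory cytokines) to 0.72 (endocardial markers), against the preset 0.01.

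The 2 shares called became 1 with doublets kept, 0 by marker score and 0 without any 1 library. The adipocyte-like share had 3.77 with doublets kept, 1.76 by marker score and 2.95 to 3.96 without 1 library, and the mesothelial-like share 0.73 by marker score and 2.59 to 2.85 without 1 library. The B lymphocyte-like share had -0.081 without injured-father library 1 and up to 1.259, the Schwann-like share 0.015 without uninjured-father library 1 and down to -0.313, and the lymphatic share -0.09 without uninjured-father library 2 and up to 0.911.

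With the replicate number as a block the counts were 20 in cardiomyocyte-, 14 in endocardial-, 12 in fibroblast-, 16 in macrophage-, 3 in pericyte- (unchanged), 7 in smooth muscle- and 0 in vascular endothelial-like nuclei (667 with an unadjusted p under 0.05), 169 over all nuclei, and 5 shares, which were the adipocyte- and mesothelial-like and the unnamed nuclei, B lymphocyte-like (0.66, adjusted p = 0.0445) and T or NK lymphocyte-like nuclei (1.499, adjusted p = 0.000319, edgeR). The list calls went from 35 to 36, and the calls of endocardial markers in cardiomyocyte-like nuclei and of mitochondrially encoded genes in fibroblast-like nuclei ended. The numbers do not pair the samples by the labels.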

Other observations

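The genes in this part were chosen after their values were seen. The circadian clock list was not called in any class, none of its genes was called over all genes, and its members ran both ways over classes that come from the same 4 hearts. Adjusted over the list alone, 1 gene was higher in cardiomyocyte-like nuclei (Arntl), and 1 was higher (Arntl) and 1 lower (Per3) in pericyte-like nuclei. Arntl, an activator of the clock, was positive in 5 of 6 classes (between -0.29 and 1.34), and Clock and Npas2 in 6 of 7. Among repressors, Nr1d1 was negative in 6 of 6 (between -0.86 and -0.07), Per3 in 6 of 7 and Per1 in 5 of 7, while Per2 was positive in 5 of 7 (between -0.14 and 0.60), Cry1 in 4 of 5 and Nr1d2 in 5 of 7. Cry2 was positive in 3 and negative in 4 classes, and Bhlhe40 positive in 3 and negative in 2. Dbp, a clock output gene, was negative in 5 of 5 (between -0.69 and -0.16), Tef in 6 of 7 and Hlf in 5 of 7. Bhlhe41 was negative in 3 of 3 classes and Ciart in 2 of 3, and Nfil3 was positive in 1 of 2.

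Nppa, which encodes atrial natriuretic peptide, was positive in 7 of 7 classes (between 0.40 and 1.73) with 0 calls, but injured-father library 2 was the highest library in each of them, and both injured-father libraries lay above both uninjured-father libraries in 4 of 7. Fgf12 was positive in 7 of 7 (between 0.92 and 1.84), with the libraries apart in 7, and 1 call, in endocardial-like nuclei. H2-K1, which presents antigens, was positive in 6 of 6 classes (between 0.29 and 0.77) and the imprinted gene Peg3 in 7 of 7 (between 0.11 and 0.89), each with 0 calls and with the libraries apart in 5 and 3 classes. Gphn was positive in 7 of 7 classes (between 0.17 and 0.28), with the libraries apart in 3. In macrophage-like nuclei Gpnmb had 0 UMIs in both injured-father libraries and 65 and 7 in the uninjured-father libraries (adjusted p = 0.396, edgeR).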
